A study of Mus musculus with 15 samples.

How the data were processed

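RNA from the whole aorta of 15 mice was profiled on Illumina mouse BeadChips with Cy3-labelled cRNA, 1 array per mouse. All mice carried the targeted Ldlr allele on a C57BL/6 background, which disposes to atherosclerosis. The labels give 8 mice homozygous for the hypomorphic Adam17 allele (ex/ex; 4 females and 4 males) and 7 with the unmodified gene (wt/wt; 3 females and 4 males). Age, diet, the stretch of aorta taken and how far surrounding fat was trimmed are not stated.

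Per the file headers, the authors deposited a non-normalized table of the signal intensity of 25697 probes on each array. The authors used BeadStudio, per the labels, with no version given. On every array 24.0% to 28.5% of the intensities were negative, so a background had already been subtracted. Beside each intensity the deposited table gives a detection p-value, and these p-values step by 1 part in 798, as a rank among that many negative control probes would. The authors also deposited a value table of 25605 probes, whose intensity is on a linear scale. It has the same distribution on every array, with a median between 87.5 and 87.6 and a minimum of 72.2, as quantile normalization gives. Within each array it kept the order of the non-normalized intensity (Spearman correlation 1). All 15 columns of the value table matched their own array best over 4888 bright probes. The tool that made this table is not stated.

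The non-normalized intensity was background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, which fits the background from the detection p-value, with an offset of 16 before log2. A probe was kept when its detection p-value was under 0.05 on at least 3 arrays, whichever group they came from. This left 14086 probes, of which 13186 carried a gene symbol. Of all probes on the array, 23890 had 1 symbol and 1807 had no listed gene. The RefSeq gene table for the mouse assembly GRCm38.p6 held the gene identifiers of 23874 probes, served to check names and to order genes along chromosomes, and changed 0 symbols. Each gene was represented by its probe with the highest mean over all arrays, which gave 9933 genes, 2423 of them with more than 1 usable probe. Log2 intensity is compressed near the background, so folds of dim genes are underestimates.

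A limma model with a mean for each of the 4 groups of genotype and sex was fitted to every gene. From it came 5 comparisons: ex/ex against wt/wt averaged over the sexes, the same in females, the same in males, the difference between these (female effect minus male effect), and males against females averaged over the genotypes. Tests were two-sided with moderated variances, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 difference is that of this model, and spreads of groups are standard deviations (SD). The 43 gene lists were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the lists, and again with a correlation estimated for each list. They were tested also with fry of limma, a rotation test of whether a list's genes move, on balance, one way. All 43 lists had at least 5 measured members. A list score is the mean of a list's members on an array after each gene was centred on its mean over all arrays. Scores were compared by exact permutation of genotype within sex, two-sided, over 2450 regroupings for both sexes, 35 for females and 70 for males.

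The comparisons, lists, thresholds, filter and the rule for naming genes were set before the data were examined. The rule names Adam17 and 8 genes of its pathway whatever their values, then the largest changes past the threshold in each direction. Where few passed, it names the smallest p-values as values only. It also names members with the largest difference, 4 for each list past the threshold over both sexes and 3 in the other comparisons. A gene or probe named outside this rule is marked where it appears.

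In 10 simulated sets with 200 changed genes among 9933, the procedure was tested with each gene's own mean and spread, drawn independently. Over both sexes it recovered 54.3% of genes changed by 1.5-fold, 90.0% at 2-fold and 97.4% at 3-fold, with 4.56% of its calls false. In females alone the shares were 22.4%, 66.6% and 90.5%, with 5.47% of calls false, and in males alone 26.3%, 74.9% and 92.0%, with 4.46%. The Benjamini-Hochberg cutoff is looser with 200 changed genes than with few. Where fewer genes truly change these shares are too high, and in the real data 7 of 9933 genes passed over both sexes. A list shifted by 0.5 log2 was found in 10 of 10 sets with either correlation, with 1 other list called. These simulated genes were uncorrelated, so the result does not show how either list test fares with correlated genes. The number of arrays limits the precision of every value.

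Replicate numbers were checked for pairing by correlating the residuals of the ex/ex and the wt/wt array of a number. The 3 numbers shared by females gave correlations of 0.440, 0.362 and 0.343, each the best match of its number. The 4 in males gave 0.145, 0.199, 0.00289 and -0.223, of which only 0.199 was a best match. The labels do not say that an equal number marks a pair, so the female pairs named below are inferred from these same data. A block for the replicate number was therefore run as an alternative, within each sex for the genotype comparisons, so that males were paired too. The alternatives also covered other background corrections and normalizations, the deposited value table, other filters, probe rules, variance models and designs, array weights, the set tests and each array left out in turn. A block for the slide was not run, because no slide or position is given. After the data were seen, 3 more were added: an adipocyte score as a covariate, and leaving out the pair of arrays with the highest adipocyte or macrophage score.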

Results

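The aortas of 15 Ldlr-deficient mice were profiled, 1 array per mouse: 4 ex/ex females, 3 wt/wt females, 4 ex/ex males and 4 wt/wt males. ADAM17 is the membrane protease that sheds TNF and both of its receptors, and ex/ex mice carry a hypomorphic allele of its gene. Each array detected between 10929 probes (wt/wt male 2) and 13176 (ex/ex male 1) above background. The mean number was 12375 ± 493 (SD, n = 8) for ex/ex and 11960 ± 633 (SD, n = 7) for wt/wt. Log2 intensities of arrays of the same group correlated between 0.944 and 0.993, across probes, against 0.916 to 0.993 for any pair of arrays. The first principal component held 29.5% of the variance and the second 21.2%.

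The first comparison asked which transcripts differ in the aorta when Adam17 is hypomorphic, over both sexes. Adam17 itself fell, from 7.52 ± 0.23 (SD, n = 7) log2 intensity in wt/wt to 6.67 ± 0.28 (SD, n = 8) in ex/ex, a log2 difference of -0.87 (SE 0.14, 1.82-fold lower, limma adjusted p = 0.0284). The highest ex/ex array (7.14) lay below the lowest wt/wt array (7.31). Its single probe, ILMN_2594718, was detected on all arrays, and where it lies relative to the altered part of the gene is not known from the files. Altogether 7 of 9933 genes passed, 3 higher and 4 lower in ex/ex, and 878 had an unadjusted p under 0.05.

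Higher in ex/ex were Trappc12, which encodes a subunit of a vesicle tethering complex, and Serpina1b and Serpina1d, which encode forms of the protease inhibitor alpha-1-antitrypsin. Trappc12 (ILMN_2502614) rose from 4.71 ± 0.25 to 5.51 ± 0.11 log2 intensity, by 0.77 (SE 0.10, adjusted p = 0.00536). Serpina1b (ILMN_2659680) rose by 1.25 (SE 0.18, 2.38-fold, adjusted p = 0.0204) and Serpina1d (ILMN_1225570) by 1.06 (SE 0.17, 2.09-fold, adjusted p = 0.0284). For these 3 genes every ex/ex array lay above every wt/wt array. Lower besides Adam17 were Mboat2, Twistnb and Mia, which encode a lysophospholipid acyltransferase, a subunit of RNA polymerase I and a small protein secreted by cartilage. Mboat2 (ILMN_1229343) fell from 5.04 ± 0.11, detected on 7 of 7 wt/wt arrays, to 4.36 ± 0.07, detected on 1 of 8 ex/ex arrays, a difference of -0.68 (SE 0.08, adjusted p = 0.00373). A second usable Mboat2 probe, dim on all arrays, gave -0.05 (SE 0.08). Twistnb (ILMN_1231779) differed by -1.36 (SE 0.22, adjusted p = 0.0284), with overlap between the groups. Mia (ILMN_2880657) differed by -0.92 (SE 0.16, adjusted p = 0.0465), with every ex/ex array below every wt/wt array. Fhdc1 (+0.74, SE 0.14, adjusted p = 0.119), Ahsg (+1.08, SE 0.22, adjusted p = 0.207) and Sntg2 (-1.10, SE 0.22, adjusted p = 0.144) came next in their direction and did not pass.

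Of the 7 genes, 6 (all but Mia) lie on the chromosome that carries Adam17, which holds 323 of the 9930 tested genes with a position (3.25%; Fisher's exact test without Adam17, p = 2.03e-07). This test was not set beforehand. It takes the genes as independent, though Serpina1b and Serpina1d are related neighbours, so its p-value may be too small. Counted in tested genes along that chromosome, Mboat2 is number 4 after Adam17, Trappc12 number 12 and Twistnb number 29, while Serpina1b and Serpina1d are numbers 224 and 225. Leaving out ex/ex female 1 raised the count to 14 genes. It fell to 2 (Mboat2 and Trappc12) without wt/wt female 1, ex/ex female 2, wt/wt female 2, ex/ex female 3, wt/wt male 1 or wt/wt male 3, to 3 without ex/ex male 1 or ex/ex male 2, and to 4 without ex/ex male 3 or wt/wt male 4. Serpina1b lost its call without the same 6 arrays, and Serpina1d without those and ex/ex male 1 and ex/ex male 2. Twistnb kept its call only without ex/ex female 1, wt/wt female 3 or ex/ex female 4, and Mia only without ex/ex female 1 or ex/ex female 4. Adam17 kept its direction with every array left out, between -0.94 and -0.77, but its adjusted p stayed under 0.05 only without ex/ex female 1, wt/wt female 3, ex/ex female 4 or ex/ex male 4. The count was 0 with a block for the replicate number (limma adjusted p = 0.0627 for Adam17, Mboat2 and Trappc12) and 0 without ex/ex male 2 and ex/ex female 3, the arrays with the highest adipocyte score, and 32 with array weights.

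**Figure D1:**
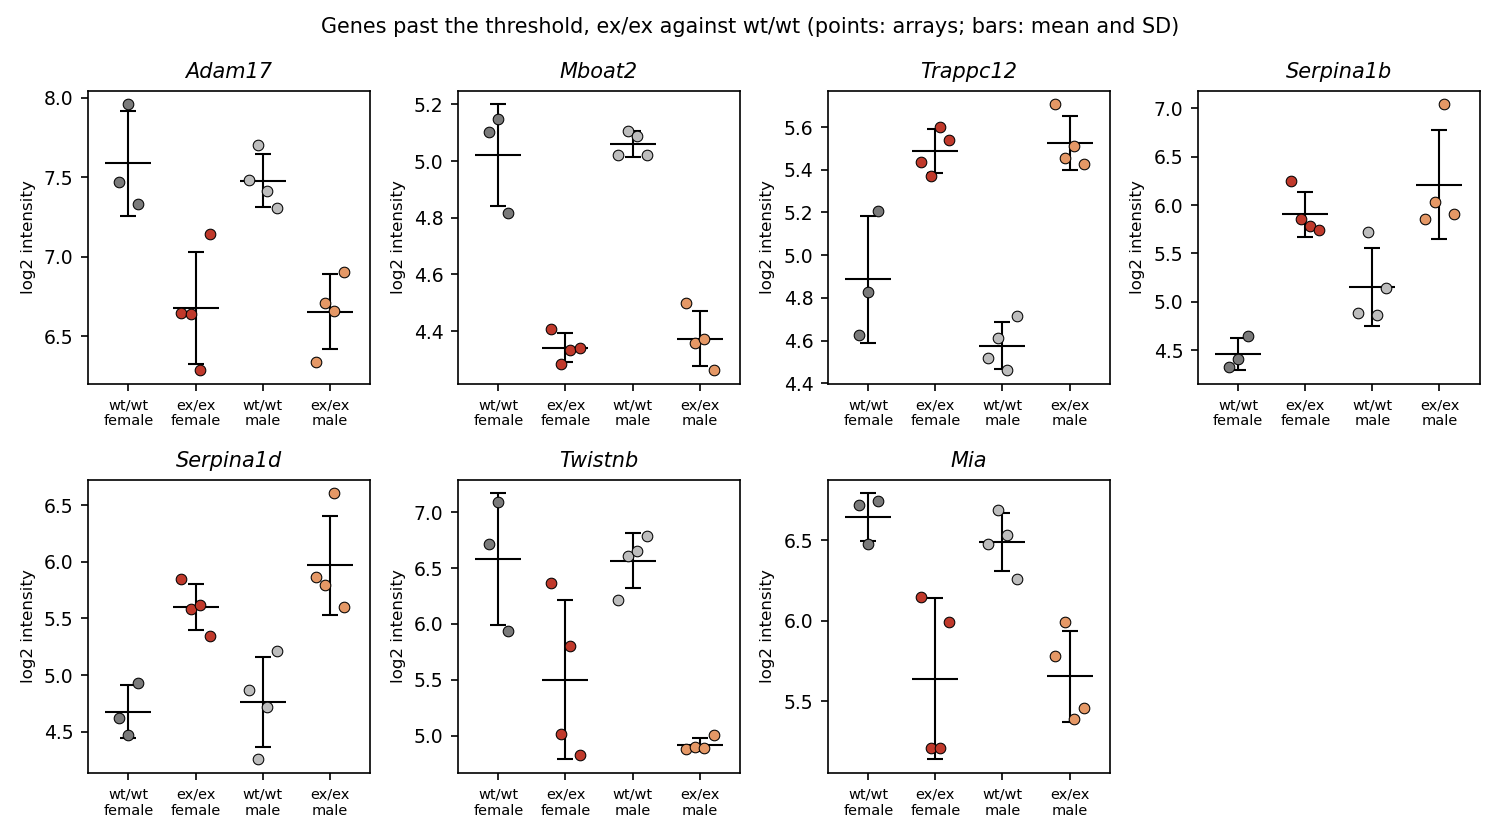
Log2 intensity of the 7 genes past the threshold over both sexes, by group, with each array as a point and the mean and SD as bars. Adam17, Mboat2 and Mia sit lower on every ex/ex array than on every wt/wt array, Trappc12, Serpina1b and Serpina1d sit higher, and Twistnb overlaps.

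**Figure D2:**
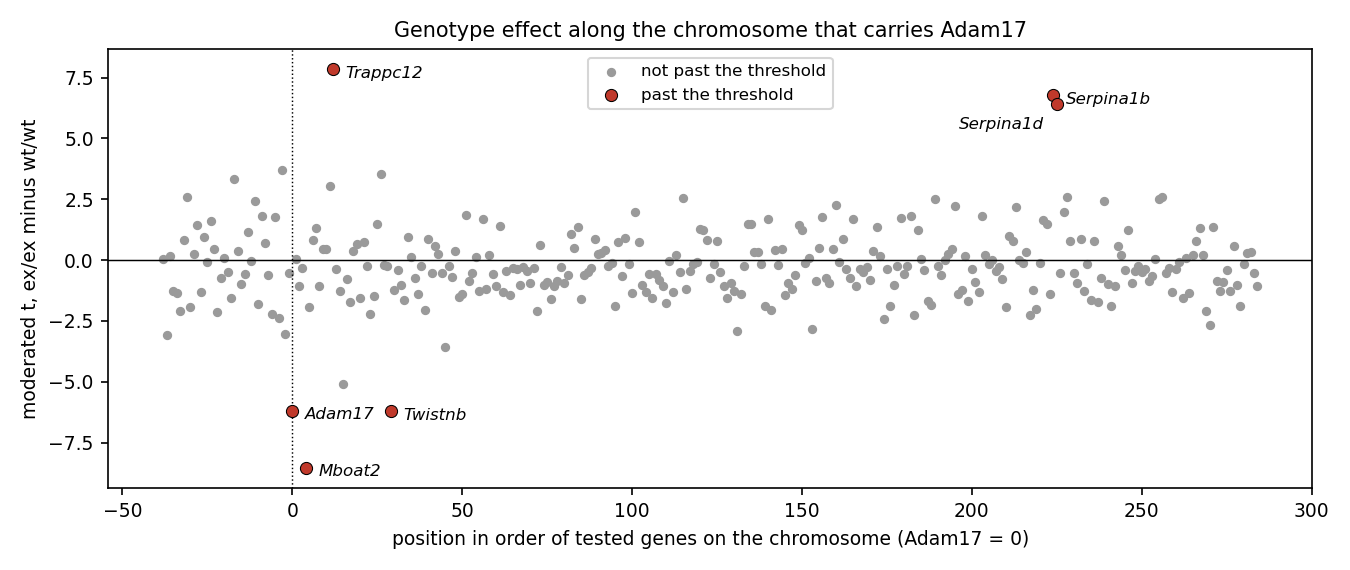
Moderated t of ex/ex against wt/wt for the tested genes of the chromosome that carries Adam17, in chromosome order, with the 6 genes past the threshold marked. Mboat2, Trappc12 and Twistnb lie within 29 tested genes of Adam17, and the Serpina1 pair lies further along.

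Among the genes of the study's pathway, none besides Adam17 passed. Timp3, the tissue inhibitor of ADAM17, was 11.91 ± 0.23 in ex/ex and 11.58 ± 0.21 in wt/wt, a difference of +0.32 (SE 0.12) that did not pass after adjustment. A dimmer second Timp3 probe, detected on all arrays, gave +0.11 (SE 0.175). The iRhom genes Rhbdf1 and Rhbdf2, whose products carry ADAM17 to the surface, differed by +0.02 (SE 0.12, adjusted p = 0.974) and -0.06 (SE 0.09, adjusted p = 0.883). The TNF receptor gene Tnfrsf1a differed by +0.09 (SE 0.12, adjusted p = 0.854), close to background on most arrays. Tnf was detected on 1 of 8 ex/ex and 0 of 7 wt/wt arrays, and both probes of the second TNF receptor gene, Tnfrsf1b, and the Adam10 probe on 0 arrays, so no difference could be measured for them. No probe is listed for Ldlr.

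The gene lists asked which cell types and pathways shifted together. At camera's preset correlation 25 of 43 lists passed and 22 of them were higher in ex/ex. With an estimated correlation 0 lists passed (lowest adjusted p = 0.279 with an estimated correlation) and with fry 0 (lowest adjusted p = 0.273), so these calls rest on the preset. In none of these 25 lists did a member pass over all genes tested. Macrophage markers had a median difference of +0.81, with 19 of 20 measured members higher in ex/ex (adjusted p = 1.10e-10, and adjusted p = 0.301 with an estimated correlation). The lysosomal protease gene Ctss was at +1.46 (SE 0.52), Cd84 at +1.32 (SE 0.45) and the complement gene C1qb at +1.07 (SE 0.40). Of the macrophage markers, 0 passed adjusted over the list alone. Foam cell and lesional macrophage genes had a median of +0.72, with 18 of 20 higher (adjusted p = 4.56e-09, and adjusted p = 0.292 with an estimated correlation). Of them 1 passed adjusted over the list alone, the lipid droplet gene Plin2 (+1.37, SE 0.35), beside Mmp12 at +1.52 (SE 0.61) and Trem2 at +1.39 (SE 0.52). The macrophage score was 0.365 ± 0.775 (SD, n = 8) in ex/ex and -0.417 ± 0.523 (SD, n = 7) in wt/wt, and the difference within sex, 0.75, had an exact permutation p = 0.0641.

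Targets of TNF receptors and NF-kB had a median of +0.26, with 21 of 27 higher (adjusted p = 1.81e-05, and adjusted p = 0.279 with an estimated correlation). Tnfaip2 was at +1.03 (SE 0.40), the chemokine gene Cxcl1 at +0.92 (SE 0.42) and the adhesion molecule gene Icam1 at +0.79 (SE 0.23). Of the targets 1 (Bcl3) passed adjusted over the list alone. Chemokines and receptors had a median of +0.49, with 20 of 24 higher (adjusted p = 1.41e-06, and adjusted p = 0.301 with an estimated correlation), Ccl5 at +1.21 (SE 0.34), Ccl9 at +1.17 (SE 0.50) and 2 (Ccl5 and Cxcl12) passing adjusted over the list alone. Endothelial markers had a median of +0.32, with 20 of 22 higher (adjusted p = 4.56e-09, and adjusted p = 0.279 with an estimated correlation). The sialomucin gene Emcn, at +1.21 (SE 0.26), was the 1 endothelial marker that passed adjusted over the list alone. The endothelial score differed by 0.40 within sex (exact permutation p = 0.0122) and the TNF target score by 0.26 (exact permutation p = 0.0286). Adjusted over the 43 scores, no permutation p was under 0.241.

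The other higher lists are given with their median difference, the members higher in ex/ex and the adjusted p. Among immune lists, MHC class II genes had +0.58, 11 of 11 (adjusted p = 9.18e-06), interferon response genes +0.25, 21 of 24 (8.27e-07), and complement genes +0.30, 11 of 12 (6.45e-05), or adjusted p = 0.301, 0.292 and 0.279 with an estimated correlation. Leukocyte adhesion molecules had +0.24, 13 of 16 (6.22e-04), resident adventitial macrophage genes +0.19, 10 of 14 (0.0400), and T cell markers +0.19, 9 of 13 (0.00804), or adjusted p = 0.279, 0.545 and 0.362 with an estimated correlation. Among lipid and energy lists, brown adipocyte markers had +0.57, 14 of 16 (1.81e-05), white adipocyte markers +0.40, 19 of 20 (9.18e-06), and cholesterol efflux and LXR genes +0.37, 16 of 16 (1.00e-05), or adjusted p = 0.301, 0.362 and 0.279 with an estimated correlation. Fatty acid oxidation genes had +0.31, 18 of 21 (1.78e-04), oxidative phosphorylation genes +0.16, 31 of 36 (3.89e-04), and hypoxia and glycolysis genes +0.18, 16 of 18 (0.00330), or adjusted p = 0.401, 0.545 and 0.279 with an estimated correlation. Some of these averages join opposite directions. The white adipocyte, brown adipocyte and fatty acid oxidation scores differed by -0.31, -0.43 and -0.21 in females and by +1.35, +1.57 and +0.84 in males. Matrix metalloproteinases and elastases had +0.24, 12 of 16 (0.00160), adventitial fibroblast markers +0.18, 20 of 23 (1.62e-04), and immediate early genes +0.14, 16 of 23 (0.0208), or adjusted p = 0.338, 0.362 and 0.362 with an estimated correlation. ADAM17 substrates had +0.06, 21 of 33 (0.0101), and ADAM17 regulators and related proteases +0.13, 14 of 17 (0.0137), or adjusted p = 0.326 and 0.279 with an estimated correlation. Adjusted over the list alone, 1 T cell marker (Thy1, +0.86, SE 0.20) and 1 fibroblast marker (Ly6c1, +1.13, SE 0.29) passed, and 0 in the other lists of this paragraph.

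Lower in ex/ex were the lists of cardiac muscle markers (median -0.46, 0 of 11 higher, adjusted p = 2.15e-04, and adjusted p = 0.326 with an estimated correlation) and mast cell markers (median -0.45, 2 of 8 higher, adjusted p = 0.0101, and adjusted p = 0.401 with an estimated correlation). Both differences lay mainly in females. The cardiac score differed by -0.85 in females (exact permutation p = 0.114) and by -0.10 in males (exact permutation p = 0.6). The mast cell score differed by -0.68 in females (exact permutation p = 0.0286) and by +0.04 in males (exact permutation p = 0.914). Contractile smooth muscle genes were lower as well (median -0.22, 1 of 20 higher, adjusted p = 7.34e-04, and adjusted p = 0.401 with an estimated correlation), with Cald1 at -0.61 (SE 0.27). Adjusted over the list alone, 6 mast cell markers passed, 5 lower and 1 higher, among them the carboxypeptidase gene Cpa3 (-1.08, SE 0.30), and 0 cardiac or contractile genes. The remaining 18 lists did not pass. Their adjusted p values were 0.814 for EGFR ligands and receptors, 0.134 for B cells and plasma cells, 0.862 for neutrophils, 0.428 for erythroid and blood markers, 0.259 for platelets, 0.148 for smooth muscle modulation and matrix, 0.814 for chondrocyte and calcification genes, 0.679 for skeletal muscle and 0.114 for Schwann cells and neurons. They were 0.679 for mesothelium, 0.414 for the cell cycle, 0.468 for apoptosis regulators, 0.582 for cholesterol synthesis, 0.691 for TGF-beta and BMP targets, 0.184 for the Notch pathway, 0.294 for heat shock, 0.814 for the circadian clock and 0.274 for Y-linked and X-inactivation genes. In the chondrocyte list 1 member, Mia, passed over all genes. Median and test differed in sign for the chondrocyte and Notch lists, and mean and test for the TGF-beta list.

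Some of these calls ended when a single array was left out: ADAM17 substrates without ex/ex female 2 or wt/wt female 3, ADAM17 regulators without wt/wt female 3, T cell markers without ex/ex male 2, mast cell markers without ex/ex female 1 or wt/wt female 2, and oxidative phosphorylation without ex/ex female 3 or ex/ex male 2 (median +0.05 for the last). Resident adventitial macrophage genes lost theirs without any of 7 arrays (wt/wt female 1, ex/ex female 2, ex/ex female 3, wt/wt female 3, ex/ex male 1, wt/wt male 3, ex/ex male 3) and immediate early genes without any of 5 (ex/ex female 2, wt/wt female 3, ex/ex female 4, ex/ex male 1, wt/wt male 3).

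**Figure D3:**
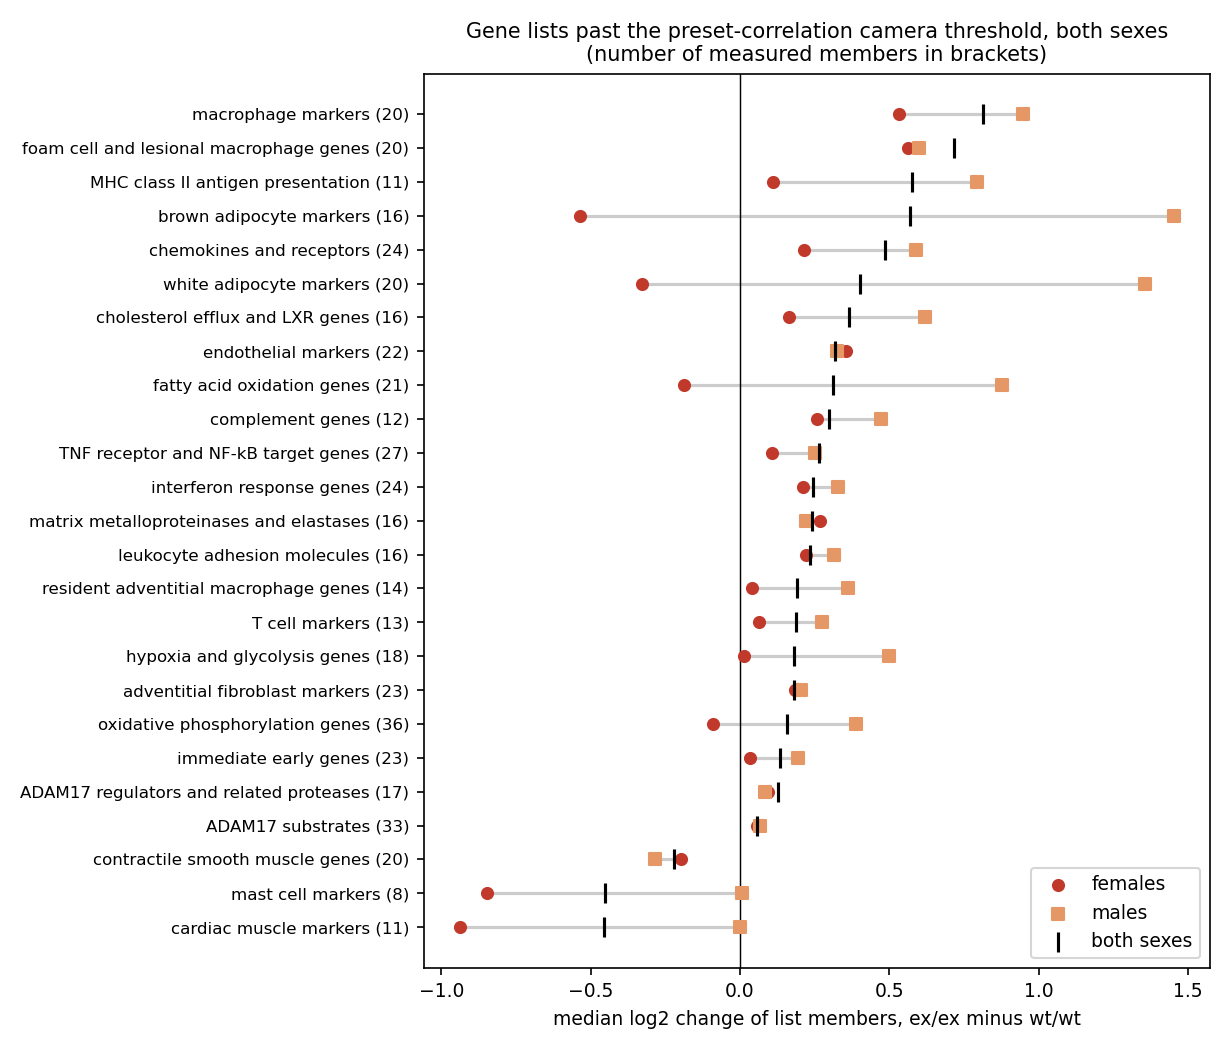
Median log2 difference, ex/ex minus wt/wt, of the 25 gene lists past the threshold over both sexes at camera's preset correlation (circles, females; squares, males; bars, both sexes). Macrophage markers reach +0.81 and cardiac muscle markers -0.46 over both sexes, and no list passed with an estimated correlation.

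**Figure D4:**
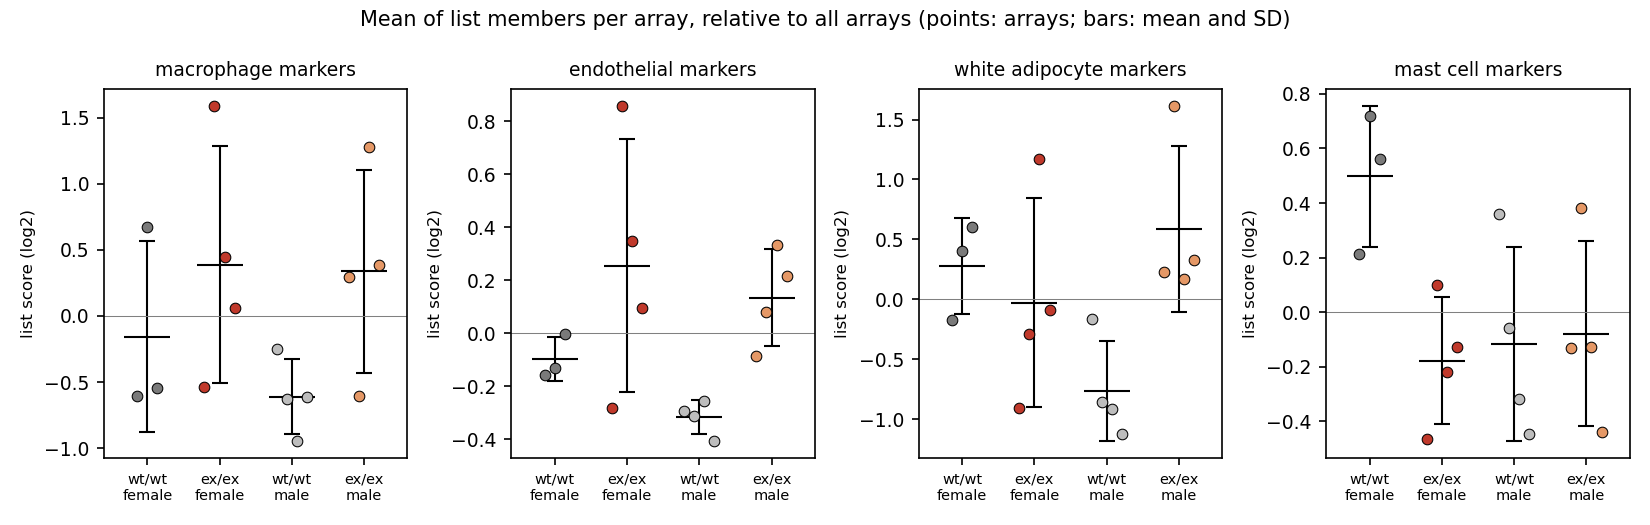
Scores of macrophage, endothelial, white adipocyte and mast cell markers (mean of centred log2 intensity), with arrays as points and the mean and SD of each group as bars. Macrophage scores of ex/ex arrays range widely, with ex/ex female 2 at 1.59 and ex/ex male 2 at -0.60.

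The second comparison asked the same question in females, 4 ex/ex against 3 wt/wt. No gene passed in limma (0 of 9933, with 376 at an unadjusted p under 0.05), and leaving out ex/ex male 3, which enters through the shared variance, gave 1. The smallest p-values were those of Serpina1b (+1.45, SE 0.27, adjusted p = 0.275), Meox1 (+0.89, SE 0.20) and Isl1 (+0.99, SE 0.23) among higher genes, and of Pdp2 (-0.87, SE 0.14, adjusted p = 0.174), Mboat2 (-0.68, SE 0.12, adjusted p = 0.174) and Armc6 (-0.60, SE 0.13) among lower ones.

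In females 12 lists passed at the preset correlation, 9 higher and 3 lower, and 0 with an estimated correlation or with fry. Cardiac muscle markers had a median of -0.94, with 0 of 11 higher (adjusted p = 2.19e-08, and adjusted p = 0.498 with an estimated correlation), Sln at -1.41 (SE 0.62) and Myh6 at -1.23 (SE 0.47). Mast cell markers had a median of -0.85, with 2 of 8 higher (adjusted p = 1.21e-05, and adjusted p = 0.498 with an estimated correlation). Adjusted over the list alone 6 of them passed, 5 lower and 1 higher, with Cpa3 at -1.60 (SE 0.44), Tpsb2 at -1.09 (SE 0.24) and Mcpt4 at -1.03 (SE 0.25). Endothelial markers had a median of +0.36, with 19 of 22 higher (adjusted p = 2.50e-05, and adjusted p = 0.729 with an estimated correlation), and Emcn (+1.45, SE 0.38) passed adjusted over the list alone. Macrophage markers had a median of +0.53 and foam cell genes of +0.56, each with 19 of 20 higher (adjusted p = 2.75e-04 and 2.46e-04, and adjusted p = 0.741 with an estimated correlation for both). The other 7 were interferon response genes (+0.21), leukocyte adhesion molecules (+0.22), matrix metalloproteinases (+0.27), ADAM17 regulators (+0.09), fibroblast markers (+0.18), chemokines (+0.21) and contractile smooth muscle genes (-0.20). Their adjusted p with an estimated correlation lay between 0.498 and 0.741, and 0 of their members passed adjusted over the list alone.

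Of the 12 calls in females, only those of the cardiac and mast cell lists held with every array left out. Without ex/ex female 2, the array with the highest macrophage score, the other 10 ended and the count was 3. Without wt/wt female 1 the count was 7, and the macrophage, foam cell, chemokine, adhesion, contractile, metalloproteinase and ADAM17 regulator calls ended. Fibroblast and ADAM17 regulator calls ended also without wt/wt female 2 or ex/ex female 3, fibroblast, chemokine and contractile calls without wt/wt female 3, chemokine and contractile calls without wt/wt male 4 or ex/ex male 4, and the chemokine call without wt/wt male 2. Without ex/ex female 2 the macrophage median was +0.12, and those of chemokines and contractile genes changed sign (-0.02 and +0.08).

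The third comparison was made in males, 4 ex/ex against 4 wt/wt. Trappc12 rose from 4.58 ± 0.11 (SD, n = 4) to 5.53 ± 0.13 (SD, n = 4), a log2 difference of +0.95 (SE 0.13, limma adjusted p = 0.0367), and was the 1 gene of 9933 that passed, with 1553 at an unadjusted p under 0.05. Mboat2 (-0.69, SE 0.11, adjusted p = 0.0685), Lrrn1 (-1.28, SE 0.22, adjusted p = 0.112), Twistnb (-1.64, SE 0.30, adjusted p = 0.123), Serpina1d (+1.21, SE 0.23, adjusted p = 0.130) and Fhdc1 (+0.94, SE 0.19, adjusted p = 0.164) did not pass. The call of Trappc12 held without ex/ex female 1, wt/wt female 1, ex/ex female 2 or wt/wt female 3 and ended without each of the other 11 arrays (adjusted p up to 0.271, without wt/wt male 3). The count was 2 without ex/ex female 1, 3 without ex/ex female 2 or wt/wt female 3, 35 when only the male arrays were fitted, and 551 with array weights. It was 0 with quantile normalization without a background model, normexp, a median shift, the deposited values, a variance trend and robust fit, or the block, and Trappc12 passed in 10 of 30 settings in all. The array weights ranged from 0.299 (wt/wt female 3) to 3.08 (wt/wt female 1).

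Adipocyte genes differed most in males. White adipocyte markers were higher in ex/ex in 20 of 20 members, with a median of +1.36 (adjusted p = 4.90e-11, and adjusted p = 0.405 with an estimated correlation), and 14 passed adjusted over the list alone against 0 over all genes. Dgat2, which encodes an enzyme of triglyceride synthesis, was at +2.83 (SE 0.73) and the lipid droplet gene Cidec at +2.69 (SE 0.62). Brown adipocyte markers were higher in 15 of 16, with a median of +1.45 (adjusted p = 3.66e-10, and adjusted p = 0.398 with an estimated correlation). Of these, 11 passed adjusted over the list alone, with Ucp1, the uncoupling protein of brown fat, at +4.35 (SE 0.92), from 5.47 in wt/wt to 9.82 in ex/ex. Fatty acid oxidation genes were higher in 19 of 21, with a median of +0.88 (adjusted p = 4.27e-08, and adjusted p = 0.426 with an estimated correlation), 10 passing adjusted over the list alone. White and brown adipocyte scores each gave an exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow.

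Macrophage markers in males had a median of +0.95, with 20 of 20 higher (adjusted p = 1.57e-07, and adjusted p = 0.449 with an estimated correlation), C1qb at +1.71 (SE 0.55) and Ctss at +1.56 (SE 0.71), and 0 passed adjusted over the list alone. MHC class II genes had +0.79, 11 of 11 higher (adjusted p = 1.80e-05, and adjusted p = 0.426 with an estimated correlation), with Cd74 at +1.60 (SE 0.56). In all 21 lists passed, 20 higher and 1 lower, and 0 with an estimated correlation or with fry. The others higher were oxidative phosphorylation (+0.39), chemokines (+0.59), foam cell genes (+0.60), cholesterol efflux genes (+0.62), endothelial markers (+0.33), TNF and NF-kB targets (+0.25), hypoxia and glycolysis (+0.50), interferon response (+0.33), complement (+0.47), fibroblast markers (+0.21), immediate early genes (+0.19), T cell markers (+0.28), ADAM17 substrates (+0.07), heat shock genes (+0.17) and adhesion molecules (+0.31). Contractile smooth muscle genes were lower (-0.28). With an estimated correlation the adjusted p of these 16 lay between 0.398 and 0.577. Adjusted over the list alone, members passed among endothelial markers (3), cholesterol efflux genes (3), foam cell genes (2), chemokines (1), fibroblast markers (1), T cell markers (1) and adhesion molecules (4, of which 2 were higher).

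With the adipocyte score as a covariate, the medians of fatty acid oxidation and oxidative phosphorylation genes in males were -0.17 and -0.27. The T cell call in males ended without ex/ex male 2 (median +0.03), wt/wt male 1, wt/wt male 3 or wt/wt male 4. The contractile call ended without wt/wt male 1, wt/wt male 3, ex/ex male 3 or wt/wt male 4, the fibroblast call without ex/ex male 1, wt/wt male 2 or ex/ex male 3, and the immediate early call without ex/ex male 1 or wt/wt male 3. The heat shock call ended without wt/wt male 1, ex/ex male 1, wt/wt male 2, wt/wt male 3 or ex/ex male 4. The ADAM17 substrate call held with 9 of 15 arrays left out in turn and the adhesion molecule call with 6.

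The fourth comparison asked whether the effect of genotype differed between the sexes. Pdp2, which encodes a phosphatase that activates pyruvate dehydrogenase, was the 1 gene of 9933 that passed (970 at an unadjusted p under 0.05). It was 8.41 ± 0.12 (SD, n = 4) in ex/ex females against 9.28 ± 0.13 (SD, n = 3) in wt/wt females, and 8.95 ± 0.17 (SD, n = 4) in ex/ex males against 8.44 ± 0.21 (SD, n = 4) in wt/wt males. The female effect minus the male effect was -1.39 (SE 0.20, limma adjusted p = 0.0355). The call held without ex/ex male 1 (adjusted p = 0.0494) and without wt/wt male 2 (adjusted p = 0.0162) and ended without each of the other 13 arrays (adjusted p up to 0.224, without wt/wt female 1). It ended also with a block for the replicate number (adjusted p = 0.191), quantile normalization without a background model, a median shift and probes averaged (adjusted p = 0.412), and passed in 9 of 29 settings in all.

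For 9 lists the effect was lower in females than in males at the preset correlation, and for 0 with an estimated correlation (lowest adjusted p = 0.759) or with fry. White adipocyte markers differed by a median of -1.55, with 20 of 20 lower (adjusted p = 2.67e-10, and adjusted p = 0.759 with an estimated correlation), Dgat2 at -3.67 (SE 1.08). Brown adipocyte markers differed by -1.87, with 15 of 16 lower (adjusted p = 1.52e-09, and adjusted p = 0.759 with an estimated correlation), Ucp1 at -5.18 (SE 1.36). Adjusted over the list alone, 7 white and 11 brown markers passed, against 0 over all genes. Fatty acid oxidation (-0.96), oxidative phosphorylation (-0.54), hypoxia and glycolysis (-0.39), cardiac muscle (-0.90), skeletal muscle (-0.19), mast cell (-0.99) and MHC class II genes (-0.70) made up the rest, with adjusted p between 0.759 and 0.870 with an estimated correlation. Of these, 4 mast cell markers passed adjusted over the list alone. Both adipocyte calls and those of fatty acid oxidation and oxidative phosphorylation held with every array left out. The cardiac call ended without wt/wt female 1 and the mast cell call without wt/wt female 2, while the hypoxia, MHC class II and skeletal muscle calls held in 8, 9 and 9 of 15 omissions. The count was 17 without ex/ex female 2, 14 without wt/wt female 3 and 15 without ex/ex male 2. With the adipocyte score as a covariate, the medians of fatty acid oxidation, oxidative phosphorylation and hypoxia genes changed sign (+0.26, +0.35 and +0.12).

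The last comparison, males against females over both genotypes, checks the labels and describes the sex difference. The Y-linked genes Eif2s3y (+5.25, SE 0.09, at least 29.9-fold, adjusted p = 2.85e-15), Kdm5d (+1.83, SE 0.13, at least 2.96-fold, adjusted p = 2.82e-06) and Uty (+0.64, SE 0.10, adjusted p = 0.0430) rose in males. Xist, the RNA of X inactivation, fell (-1.71, SE 0.14, at least 2.68-fold, adjusted p = 1.24e-05). These 4 of 9933 genes passed (490 at an unadjusted p under 0.05), and every array matched its labelled sex. The call of Uty held only without wt/wt female 1 (adjusted p = 0.0438) or wt/wt male 2 (adjusted p = 0.0482), and in 7 of 30 settings in all (adjusted p up to 0.300), while Eif2s3y, Kdm5d and Xist passed in each of the 30.

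Of the lists, 7 passed at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.742), while fry called 1, the Y-linked and X-inactivation genes. Higher in males were immediate early genes (median +0.16, 18 of 23 higher, adjusted p = 4.23e-05, and adjusted p = 0.742 with an estimated correlation) and TGF-beta and BMP targets (+0.10). Atf3 was at +1.27 (SE 0.40) and Fosb at +0.94 (SE 0.24), and 3 immediate early genes passed adjusted over the list alone. Lower in males were markers of cardiac muscle (-0.43), mast cells (-0.22) and endothelium (-0.16), cell cycle genes (-0.16) and interferon response genes (-0.14), with adjusted p = 0.821 with an estimated correlation for each of these and for the TGF-beta list. The immediate early and cardiac lists kept their calls with every array left out, and the others in 6 (interferon, endothelial), 8 (cell cycle), 9 (mast cell) and 10 (TGF-beta) of 15 omissions. The count was 20 without ex/ex female 1, 17 without ex/ex male 3, 4 without wt/wt male 3, 3 without ex/ex female 2, wt/wt male 2 or wt/wt male 4, and 2 without wt/wt female 2.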

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

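The tests of explanations in this part were all chosen after the results were seen.

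The largest differences between the sexes concerned fat. The interaction, female effect minus male effect of ex/ex, had a median of -1.55 log2 over 20 white adipocyte markers and -1.87 over 16 brown ones. Genes of fatty acid oxidation (-0.96), oxidative phosphorylation (-0.54) and hypoxia and glycolysis (-0.39) differed in the same direction, each past camera's threshold at the preset correlation and none with an estimated one. Of the 36 adipocyte markers, 35 were higher in ex/ex than in wt/wt males and 10 in ex/ex than in wt/wt females. Cox8b was at 10.86 in ex/ex males and 7.97 in wt/wt males, and Ucp1 at 9.82 and 5.47. The white list shares 2 genes with the foam cell list and 2 with the cholesterol efflux list, and the brown list shares 4 with fatty acid oxidation.

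The mean of both adipocyte scores was higher in ex/ex than in wt/wt males by 1.46 (SE 0.45), and its interaction was -1.83 (SE 0.668). The tables argue against a single fatty array as the whole cause, since without ex/ex male 2 the male difference was still 1.09 (SE 0.41). Fat left on the vessel at dissection may account for the pattern, but the values do not decide this. The score ranged over 1.90 within a single female group, yet a range of single arrays cannot be weighed against a difference of means. The male groups did not overlap (lowest ex/ex 0.0499, highest wt/wt -0.205), and 3 of 4 wt/wt males lay below every female. No label records how the aortas were trimmed, and an effect of genotype on perivascular fat of males stays open as untested. With the adipocyte score as a covariate the medians of fatty acid oxidation and oxidative phosphorylation genes in males were -0.17 and -0.27, in place of +0.88 and +0.39.

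Pdp2 was the 1 gene whose genotype effect differed between the sexes, by -1.39. It passed in 9 of 29 settings and not with the replicate block, a median shift, quantile normalization without a background model or probes averaged. The lists of cardiac muscle (-0.90), skeletal muscle (-0.19), mast cell (-0.99) and MHC class II genes (-0.70) had a lower effect in females than in males at camera's preset correlation and passed neither with an estimated one (adjusted p between 0.759 and 0.870) nor with fry. Splits of the arrays do not exclude chance for the count of 9 lists.

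In 11 of 162 checks, each a gene, list score or probe count in a group of 4, 1 array stood apart from the others by more than Dixon's 95% limit, while chance gives about 1 in 20. The ratio of the gap to the range of the group was 0.860 for Serpina1b in ex/ex male 3 (7.05 against 5.86 to 6.03) and 0.871 for Twistnb in ex/ex male 4 (the highest of its group). It was 0.908 for Sntg2 in wt/wt male 2 (5.53 against 6.68 to 6.80), the array with the fewest detected probes. The same array stood apart in the contractile smooth muscle score (0.909), the fibroblast score (0.883) and the hypoxia and glycolysis score (0.843), in which it was the lowest of its group. Array ex/ex male 2 stood highest in the white adipocyte score (0.891; 1.61 against 0.171 to 0.328) and the oxidative phosphorylation score (0.842). The other ratios were 0.871 for the TNF and NF-kB target score of wt/wt male 3, 0.834 for the fatty acid oxidation score of wt/wt male 1, and 0.894 for the probes detected in ex/ex male 1.

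The 900 usable probes without a listed gene entered no comparison of genes. Tested on their own with limma, 0 passed between genotypes over both sexes (62 at an unadjusted p under 0.05), in females (30), in males (113) or for the interaction (75), and 2 passed between the sexes. Probe ILMN_2899599 was 10.5 ± 0.24 (SD, n = 8) in males and 8.88 ± 0.30 (SD, n = 7) in females, a difference of +1.63 (limma adjusted p = 8.56e-06). Probe ILMN_1235995 was 4.76 ± 0.24 (SD, n = 8) in males and 4.25 ± 0.06 (SD, n = 7) in females, a difference of +0.51 (limma adjusted p = 0.0227). What either probe detects is not known from the files.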

How the results depend on the processing

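In this part the adipocyte covariate and the runs without the arrays of highest adipocyte score (ex/ex male 2, ex/ex female 3) or highest macrophage score (ex/ex female 2, ex/ex male 3) were chosen after seeing the data. The cause of a changed count was not tested unless named. A block for the slide was not run, since no slide is given. The adipocyte covariate gives no value for the adipocyte lists and their members, which make it up, and the additive and genotype-only models apply to some counts only.

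Over both sexes Mboat2 passed in 27 of 30 settings and Trappc12 in 29 of 31, Serpina1b in 20 of 31, Serpina1d in 16, Adam17 in 12, Twistnb in 11 and Mia in 7, and all kept their direction in each. Of the values of single genes in all comparisons, 7733 kept direction and side of the threshold, 157 lost a call, 64 gained 1 and 18 turned direction, and of those of called lists 1955, 255, 0 and 13. The 7 genes became 2 with normexp background, 4 with a median shift, 2 with the authors' deposited values, 2 with no filter (16554 genes tested), 32 with array weights (all 7 among them), 3 with the adipocyte covariate, 0 without the arrays of highest adipocyte score and 3 without those of highest macrophage score, and 2 to 14 with each array left out (14 without ex/ex female 1, 2 without any of 6 arrays). Adam17 lost its call at -0.66 with normexp, -0.85 with a median shift, -0.56 with the deposited values, -0.87 with no filter, -0.85 with the adipocyte covariate, -0.81 without the adipocyte arrays and -0.86 without the macrophage arrays, and ranged from -0.94 to -0.77 with each array left out (adjusted p 0.0145 to 0.248 over all settings). The dimmest of these genes lie near background (Mboat2 at 4.36 in ex/ex), where signal over background limits their folds.

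A block for the replicate number within each sex pairs the males as well as the females, though male residuals matched little. With it the count was 0 over both sexes (Adam17 -0.94), 0 in females as before, 0 in males and 0 for the interaction. The block leaves fewer degrees of freedom for the error, so these counts do not show that pairing removed the differences. Lists in females numbered 15 with the block, in place of 12.

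In females the 0 genes became 1 with the deposited values, 1 with no filter and 4 with array weights, and 0 to 1 (without ex/ex male 3) with each array left out. In males the 1 gene became 0 with quantile normalization without a background model, 0 with normexp, 0 with a median shift, 0 with the deposited values, 0 with a variance trend and robust fit, 0 with the adipocyte covariate, 0 without the adipocyte arrays and 0 without the macrophage arrays. It became 2 with no filter, 2 at an adjusted p under 0.1, 35 when only the compared groups were fitted and 551 with array weights, and 0 to 3 (without ex/ex female 2 or wt/wt female 3) with each array left out. The 1 interaction gene became 0 with quantile normalization without a background model, 0 with a median shift, 0 with probes averaged, 0 with the adipocyte covariate, 0 without the adipocyte arrays and 0 without the macrophage arrays, and 0 to 1 with each array left out. Between the sexes 4 genes became 7 with array weights and 3, without Uty, with quantile normalization without a background model, normexp, the deposited values, a stricter filter, a variance trend and robust fit, the additive model, the block, and each of the runs chosen after seeing the data, and 3 to 6 with each array left out. Each 0 here is from limma, which without any of these changes gave 878 (both sexes), 376 (females), 1553 (males) and 970 (interaction) genes at an unadjusted p under 0.05.

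With an estimated correlation 0 lists passed in each of the 5 comparisons, and with fry 0 in the 4 genotype comparisons and 1 between the sexes. At an unadjusted p under 0.05 of camera and of fry there were 7 and 6 lists over both sexes, 3 and 2 in females, 3 and 9 in males, 1 and 2 for the interaction and 1 and 2 between the sexes, of 43. Leaving out each array gave 21 to 26 lists over both sexes, 3 (without ex/ex female 2) to 18 in females, 15 to 23 in males, 6 to 17 (without ex/ex female 2) for the interaction and 2 (without wt/wt female 2) to 20 (without ex/ex female 1) between the sexes. Lists in females were 3 without the macrophage arrays, and interaction lists 14 without the adipocyte arrays and 14 without the macrophage arrays. Lists between the sexes were 2 with normexp, 4 with a median shift, 4 with the deposited values, 3 with no filter, 3 with array weights, 4 without the adipocyte arrays, 3 without the macrophage arrays and 12 at an adjusted p under 0.1.

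Directions turned for few results. Rhbdf1 over both sexes was at -0.0855 with a median shift, -0.000456 with array weights and -0.0656 without the macrophage arrays, and -0.0232 to +0.0798 with each array left out. In females, Vcam1 ranged from -0.0300 to +1.20 and Csrp1 from -0.87 to +0.0614 with each array left out, and Csrp1 was at +0.17 with array weights. The chemokine median in females ranged from -0.0222 to +0.54 with each array left out and was -0.0222 without the macrophage arrays, and the contractile median from -0.32 to +0.0793, the latter also without those arrays. With the adipocyte covariate, fatty acid oxidation medians were -0.0541 (both), -0.17 (males) and +0.26 (interaction), oxidative phosphorylation -0.10, -0.27 and +0.35, and hypoxia -0.0151 (males) and +0.12 (interaction). In males with that covariate Slc25a20 was at -0.13, Sdhb at -0.0694, Uqcrc1 at -0.30 and Aldoa at -0.26, and for the interaction Uqcrc1 at +0.0388, Sdhb at +0.38, Pfkl at +0.12 and Aldoa at +0.19. Without the adipocyte arrays the oxidative phosphorylation median over both sexes was -0.0650. The shared content of adipocyte genes with these lists was not separated from other causes. No scaling moved the median of all genes by as much as 0.1.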

Other observations

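The tests in this part were all chosen after the results were seen.

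The alpha-1-antitrypsin genes form a cluster of close relatives, and the members other than Serpina1b and Serpina1d, named here after their values were seen, were dim and differed less. Serpina1a was 4.64 ± 0.19 (SD, n = 8) in ex/ex and 4.68 ± 0.20 (SD, n = 7) in wt/wt, a log2 difference of -0.0585 (SE 0.10), and between -0.0689 and -0.00242 with other scalings, while a dimmer second probe gave +0.11 (SE 0.0516). Serpina1e differed by +0.25 (SE 0.12), with other scalings between +0.0775 and +0.31, and Serpina1c was detected on 0 arrays. A second probe of Serpina1b gave +1.01 (SE 0.17), beside +1.25 for the first. Whether the probes of b and d also bind the RNA of each other was not tested.

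Of the 7 genes past the threshold over both sexes, 6 lie on the chromosome of Adam17. A candidate explanation is DNA of another strain carried along with the targeted allele, and the 50 uncalled genes nearest to Adam17 had a mean absolute t of 1.34 against 0.994 for all uncalled genes. Only 1.02% of 8940 windows of neighbouring genes were as high, as that explanation needs for Mboat2 and Trappc12, which lie in that window. Of the windows 12.7% were as high as that around Twistnb and 45.7% as that around Serpina1b and Serpina1d. For these 3 genes the windows lend the explanation no support, and it stays open. A sequence variant under a single probe may account for some calls: of 3 called genes with a second usable probe, 2 moved the same way by over 2 standard errors (Serpina1b and Twistnb) and the dim second probe of Mboat2 did not (-0.05, SE 0.08), so for genes with 1 probe this cannot be told apart from a change of RNA. Regulation by ADAM17 itself was not tested and stays open, since every ex/ex mouse carries both the allele and its flanks.

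If the flanking DNA varied between ex/ex mice, the same arrays would stand out for neighbouring genes. For both Sntg2 and Twistnb, chosen after their values were seen, ex/ex female 1 (5.77 and 6.37) and ex/ex female 3 (5.68 and 5.80) were the highest ex/ex arrays, the next being 4.97 and 5.02. For Adam17, also lower in ex/ex, ex/ex female 4 and ex/ex male 4 were the highest ex/ex arrays. For Mboat2, lower too, ex/ex male 1 and ex/ex female 1 were the highest. The Mboat2 probe was detected on 1 of 8 ex/ex arrays, so the order of its values says little. Trappc12 was higher in ex/ex, so for it the ex/ex arrays nearest to wt/wt are the lowest ones. There ex/ex female 2 was the lowest ex/ex array, ex/ex female 1 was among the lower ones and ex/ex female 3 among the highest. No genotype of the flanks is given.

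The macrophage score was higher in ex/ex by 0.749 (SE 0.368). A lower share of smooth muscle cells would raise the markers of all other cell types. The differences of 14 cell types lay further apart (SD 0.343) than in most of the 2450 regroupings within sex (exact permutation p = 0.0371). The same held over the 560 that part the 3 female pairs, which are inferred from replicate numbers and residuals (exact permutation p = 0.00714). So the types did not shift alike, but that spread does not concern macrophages alone. Macrophage minus the mean of the 13 others was 0.647 (SE 0.388), too close to its error to set macrophages apart. A lower share of smooth muscle cells therefore stays open for the macrophage score. By their slopes within groups, the adipocyte score and the number of detected probes accounted for -0.0598 (95% interval -0.482 to 0.362) and 0.143 (-0.236 to 0.522) of the difference. The array of highest adipocyte score, ex/ex male 2, had a macrophage score of -0.602. Both intervals end below 0.749, but the SE of that difference, 0.368, leaves open whether either was the whole cause. The difference over both sexes had an exact permutation p = 0.0196 over the 560 regroupings and 0.0641 over the 2450, the score was higher in ex/ex in 3 of 3 female pairs, and with these pairs as a block the difference was 0.804 (SE 0.288), 0.992 (SE 0.336) with the adipocyte score and 0.739 (SE 0.331) with the detected probes, against 0.809 (SE 0.428) and 0.606 (SE 0.410) without the block, so a part played by either stays open. A larger or more inflamed lesion in ex/ex, the biological explanation the design offers, stays open as untested, since no lesion size is given.

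Splits of the same arrays into groups of the same sizes show how far chance goes. The count of genes over both sexes was 7 for the real groups and 4 for the highest other split. Only the real one of 100 splits reached 7, the smallest share these allow, so chance is an unlikely source of this count in the fit without a block. Of the 7 genes, 6 lie on the chromosome of Adam17, the targeted gene among them, so the count does not speak for a wider difference. At an unadjusted limma p under 0.05 the count was 878, as large in 16 of 100 splits, with 1780 in the highest other. Chance cannot be excluded for that larger count. In 100 splits drawn from the 560 that, like the real one, part the 3 female pairs, the highest other gave 1 gene. With a block for the replicate number limma called 0 genes over both sexes and 0 in males. Without the block, 4 genes passed between the sexes against 1 in the highest other split (1 of 100). These are Y-linked genes and Xist, which splits that mix the sexes must lose, so this comparison decides nothing about other genes. At an unadjusted limma p under 0.05 the count between the sexes was 490, as large in 33 of 100 splits. Chance cannot be excluded for the interaction (1 against 4, 5 of 100). In males 1 gene passed against 0 in the highest other split (1 of 35 splits, the smallest share these allow). That count rests on Trappc12, which passed in 10 of 30 settings, so chance is not excluded there. At an unadjusted limma p under 0.05 the male count was 1553, against 1045 in the highest other split. In females, where limma called 0 genes (376 at an unadjusted p under 0.05), every split gives as many (35 of 35) and the comparison decides nothing, the highest other split giving 4.

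The counts of lists at camera's preset correlation behaved otherwise, the median of the other splits being between 10 and 13.5 lists in all 5 comparisons. Over both sexes 25 lists passed, and 2 of 100 splits gave as many, the real one and another with 28. A count as large was thus rare at that correlation, but it also arose by regrouping, so chance is not excluded. With an estimated correlation 0 lists passed (7 at an unadjusted p under 0.05), and with fry 0 (6). Chance cannot be excluded for females (12 against 23, 19 of 35 splits), males (21 against 22, 4 of 35), the interaction (9 against 25, 65 of 100) or the sexes (7 against 25, 75 of 100). The preset is 0.01, while estimated correlations within lists went up to 0.806 over both sexes, and with estimated correlations no split of any comparison called more than 2 lists. The many lists in other splits thus depend on the preset. In females, if equal replicate numbers mark pairs, 8 splits part all 3 pairs, among which 4 gave as many lists as the real one and the highest other gave 15. Splits that part fewer pairs gave a median of 12 lists, against 5 for the others that part all.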
